A study of Mus musculus with 19 samples.

How the data were processed

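Mouse embryos at the 2-cell stage were profiled by RNA sequencing in 3 groups, named WT, HET and KO after the genotype labels Dux +/+, Dux +/- and Dux -/-. There were 2 WT, 15 HET and 2 KO embryos. The labels name the Smart-seq V4 ultra low input kit and Nextera XT libraries, which amplify cDNA from polyadenylated RNA and do not mark strand, and embryos were held in KSOM medium. The HET embryos came from matings between heterozygous parents per the labels. The sample titles carry an M number, which was 3 for WT, 7 for KO, 1 for HET replicate 1 and 2 for the other 14 HET embryos. What the M number stands for is not given in the sources used here, and no 2 groups share one, so it could not enter a model.

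The authors deposited 2 tables per embryo, both holding whole-number counts, 1 over genes and 1 over copies of repeats. Reads were aligned to the mm9 build with HISAT2 2.1.0 and counted with featureCounts per the submitters' processing notes, which do not say how reads with several positions were treated. The gene tables held 37991 Ensembl identifiers, of which 32919 were paired with a symbol through a GENCODE annotation, by identifier only and with no coordinates because the reference at hand is of another build. The repeat tables held 3377756 copies, 746938 of them with a count in at least 1 embryo. Their rows carry running numbers only, so repeat families, among them MERVL, were not analysed here. The tests planned for repeat families and MERVL copies were replaced by a test of single copies, chosen after the tables were seen. Gene counts summed to between 6580047 and 10097109 per embryo and repeat counts to between 710965 and 1367206. Replicates of a group differed far beyond counting noise, with a chi-square per degree of freedom of 79.1 for the WT pair, 61.7 for the KO pair and 16.9 to 65.0 for the HET pairs, so each embryo was counted as 1 sample. The labels do not say whether embryos of a group shared a litter, and p-values measure the spread between these embryos.

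Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, on the genes kept by its expression filter at a minimum count of 10, which were 16796. One model with a coefficient per group was fitted to all 19 embryos, leaving 16 residual degrees of freedom, so the HET embryos, whose pairs mostly differed less than the WT and the KO pair, set most of the estimated spread. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Standard errors were derived from the fold change and its F statistic. Levels are CPM, which scale counts to a common TMM-adjusted library total, given as mean ± SD. Where all embryos of a group had 0 counts, the fold is a lower bound against 3 counts over that group. Such floors cover counting error only, since reads carry no molecular identifiers.

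Before the data were examined, 17 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation, and with fry. The lists cover the 2-cell program that DUX activates, the Dux family, regulators of Dux, oocyte transcripts, nucleolar factors, later cleavage and lineage factors, p53 and stress responses, cytosolic ribosomal proteins, the proteasome, the respiratory chain, histones and mitochondrial genes, and markers of cumulus, sperm, blood and oviduct cells. Of the 53 names fixed for the 2-cell list, 19 had no match in the table. Named genes were, per comparison, the 12 higher and 12 lower genes with the smallest p among those called with a mean log2 CPM of at least 3, which for KO against WT also had to separate the embryos of both groups, plus up to 4 members of each list with the smallest p and all Dux family genes. Members of multicopy families share near-identical sequence, so their counts are uncertain in how they are split.

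Repeat copies were tested with the same model and gene-based scaling. Copies with fewer than 20 counts in total were removed first, and the same expression filter as for genes was then applied. The relation of Duxf3 to the 2-cell list was tested over the 15 HET embryos with Pearson and Spearman coefficients and 100000 two-sided permutations, as fixed beforehand; the part of that plan on MERVL was not run. Alternatives covered DESeq2 1.42.0, its size factors, other count filters, leaving out each WT and KO embryo, leaving out HET replicate 1, fits of 2 groups only, and a replicate block. List medians were also set against 10000 random lists matched on expression and transcript length or GC content, for oocyte genes drawn from genes not called lower, and the list less its matched genes was compared between embryos by exact permutation, two-sided by doubling. Length and GC content were those of the longest annotated transcript of each gene. These steps used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

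The gene test was checked on simulated counts with known changes. For KO against WT, with 15928 simulated genes, it recovered 3.28% of changes of 1 on the log2 scale, 22.5% of changes of 2 and 39.4% of changes of 4, with 3 false calls among 47. For KO against HET it recovered 16.9%, 43.3% and 67.6% over 15872 genes, and for HET against WT 13.0%, 45.5% and 66.7% over 15919. For repeat copies, KO against WT, it recovered 1.64% of changes of 4 over 29186 copies. A gene missing from the calls is therefore not shown to be unchanged. The simulation gave every group the same spread per gene and changed only a small part of the genes. The WT and KO pairs differed more than most HET pairs, so the false calls seen here cannot show the real error rate. The shares recovered also hold for this setting only.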

Results

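Dux encodes a homeodomain transcription factor that is expressed at the time of zygotic genome activation and can activate 2-cell genes in mouse cells. The series asked how 2-cell embryos from wild-type, heterozygous and homozygous Dux knockout crossings differ in their RNA. Gene counts per embryo summed to between 6580047 and 10097109, and between 15374 and 18478 genes had a count. The lowest number of detected genes was in KO replicate 1.

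The targeted locus was read first. Duxf3, the Dux gene of the array, had 59 and 33 counts in the WT embryos and 0 counts in both KO embryos, and the family members AW822073 and Gm4981 also had 0 counts in both. Duxf3 stood at 5.60 ± 2.47 CPM in WT (SD, n = 2) and at 2.20 ± 1.65 CPM in HET (SD, n = 15). Against the floor of 3 counts over the KO group, Duxf3 was at least 25.8-fold lower in KO than in WT, AW822073 at least 30.4-fold lower and Gm4981 at least 24.7-fold lower, with edgeR adjusted p of 0.0251, 0.0273 and 0.000445. Without WT replicate 1 the bound for AW822073 was 17.2-fold. A single KO embryo gives a higher floor, with bounds of 12.4, 14.6 and 11.9 without KO replicate 1 and 13.3, 15.7 and 12.8 without KO replicate 2. The calls of Duxf3 and AW822073 are fragile at these counts, and were lost without WT replicate 1 and without either KO replicate. Their fitted log2 fold changes were -7.945 and -7.901 without WT replicate 1, and -8.85 and -9.215 without WT replicate 2. With 0 counts in KO these are set by the prior count and the WT level, so they do not offset the lost calls. Gm4981 kept its call without any 1 of these embryos. In a fit of the 4 WT and KO embryos alone the adjusted p was 0.0824, 0.0752 and 0.0816 for the 3 genes. Among the HET embryos, replicates 3 and 10 had 0 Duxf3 counts and replicate 20 had 1, AW822073 had 0 counts in these 3, and the highest Duxf3 count was 47 in replicate 18. Gm4981 had between 13 and 78 counts in every HET embryo. The HET label therefore covers embryos with and without detectable Duxf3, and no embryo was moved between groups. For HET against WT the Duxf3 log2 fold change was -1.34 ± 1.02 (SE), with an adjusted p of 0.484.

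Most tested genes of the 2-cell program were lower in KO than in WT embryos, and part of the oocyte transcripts were higher. Of 30 tested 2-cell genes, 23 fell and 3 rose, and 6 had 0 counts in both KO embryos, with a median log2 fold change of -6.52, or -6.46 with genes absent from KO at their bound. Zfp352, a zinc finger gene of the 2-cell stage, fell from 438 ± 206 to 1.58 ± 2.23 CPM (SD, n = 2 each), a log2 fold change of -8.13 ± 0.82 (SE, adjusted p = 2e-06, edgeR). Gm8300 and Gm4027 fell too, with log2 fold changes of -7.42 ± 1.18 and -7.05 ± 1.13 (SE, adjusted p of 0.000198 and 0.00022, edgeR). These 3 genes had 0 counts in KO replicate 1, and without it their log2 fold changes were -7.12, -6.40 and -6.03. Zfp352 was at -7.54 without WT replicate 2. Pramef12, Arg2 and Sp110 were the members that rose. Without KO replicate 1, 12 members fell and the median was -5.61, and without KO replicate 2 it was -9.34. Adjusted over the list alone, 24 fell and 3 rose. The list passed camera (adjusted p = 1.25e-11) and fry (adjusted p = 0.00124), but not camera with an estimated correlation (adjusted p = 0.197).

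Of 54 oocyte transcripts, 19 rose and 0 fell in KO against WT, with a median log2 fold change of 0.49, and adjusted over the list alone 20 rose and 0 fell. Dnmt1, the maintenance DNA methyltransferase, rose from 21.7 ± 12.9 to 222 ± 33.9 CPM, and the F-box genes Fbxw16 and Fbxw20 rose by 2.89 ± 0.37 and 3.54 ± 0.60 (log2, SE). Without WT replicate 1 only 9 oocyte transcripts rose, and without WT replicate 2 the log2 fold change of Fbxw20 was 4.21. The camera adjusted p was 2.99e-06, and 0.178 with an estimated correlation. Cytosolic ribosomal protein genes went the other way: 35 of 86 fell and 1 rose, and 42 fell and 2 rose adjusted over the list alone. Rps26 and Rps13 were among them, at -3.22 ± 0.41 and -2.37 ± 0.32 (log2, SE). Without KO replicate 1, 19 fell, and without WT replicate 2, 23. The list had a median of -1.05, with a camera adjusted p of 2.88e-11, and 0.178 with an estimated correlation. In the proteasome list, 9 of 47 members rose and 1 fell, among them Psma7, which rose from 138 ± 76.5 to 918 ± 40.1 CPM, with a camera adjusted p of 0.00334, and 0.179 with an estimated correlation. This call was lost without WT replicate 1 (adjusted p = 0.117), and without WT replicate 2 the log2 fold changes of Dnmt1 and Psma7 moved from 3.35 and 2.73 to 4.14 and 3.46. The Dux family list passed camera at an adjusted p of 0.00357, and 0.179 with an estimated correlation. It holds the targeted gene, and 3 of its 5 tested members had 0 counts in both KO embryos. Its pass is therefore no result apart from the knockout.

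Other lists did not pass camera. Nucleolar factors had 10 members higher and 7 lower of 59 (adjusted p = 0.0524), with Npm1 higher by 1.26 ± 0.18 (log2, SE). Nop16 stood at -4.77 ± 0.85 (log2, SE), had 0 counts in KO replicate 2 and was at -3.79 without it. In a fit of the WT and KO embryos alone neither gene was called (edgeR adjusted p of 0.144 and 0.0944). Later cleavage and lineage factors had 3 of 33 lower (0.136), p53 targets 2 higher and 3 lower of 24 (0.409), stress genes 1 higher and 4 lower of 30 (0.136), and regulators of Dux 1 higher and 2 lower of 18 (0.425), the values in brackets being camera adjusted p. By fry, which asks whether a list moves on balance in one direction, the cleavage and stress lists passed with adjusted p of 0.032 and 0.0147. Respiratory chain genes had 8 higher and 8 lower of 78 (0.367), histones 1 higher of 22 (0.39) and mitochondrial genes 0 of 33 (0.603). Of markers of other cells, sperm had 0 of 7 called (0.387), blood 0 of 5 (0.136, and a fry adjusted p of 0.00552), cumulus cells 1 higher and 1 lower of 15 (0.553), and the oviduct list had 3 tested members with 0 called. The cumulus genes Inha and Hsd3b1 had 111 and 131 counts in KO replicate 1 and 0 each in KO replicate 2. In WT replicates 1 and 2, Inha had 23 and 0 counts and Hsd3b1 had 0 and 1. Tnfaip6 had 102 and 18 counts in WT and 109 and 10 in KO. Has2 differed from this, with 7 counts in each WT embryo and 8 and 89 in KO. Cyp19a1 had 267 and 209 counts in the KO embryos against 12 and 54 in WT, a call lost without WT replicate 1 (adjusted p = 0.19) and without KO replicate 1 (0.0727).

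Over all 16796 genes, 2059 were called between KO and WT, 994 higher and 1065 lower in KO. Of the lower genes, 226 had 0 counts in both KO embryos, among them Bex6, at least 148-fold lower, and Gm15455, at least 123-fold lower. The bound for Gm15455 was 187 without WT replicate 1 and 57.9 without WT replicate 2. With 1 KO embryo the bounds were 71.3 and 59.1 without KO replicate 1, and 76.6 and 63.5 without KO replicate 2. Gcsh, a subunit of the glycine cleavage system, fell by 5.21 ± 0.45 (log2, SE, adjusted p = 4.09e-07, edgeR), or 5.95 without KO replicate 2, and the cathepsin gene Ctsl fell from 316 ± 42.4 to 13.7 ± 1.98 CPM. B930036N10Rik, Zfp30, Gabpa, Gm5612, Platr25, Mfap5 and the gene ENSMUSG00000081808 completed the lower genes. The higher genes included Ssb, which encodes the La RNA-binding protein and rose from 311 ± 103 to 2200 ± 54.7 CPM, the Polycomb gene Pcgf1, up by 3.42 ± 0.37, and the spindle genes Aspm and Nusap1, up by 2.98 ± 0.33 and 3.29 ± 0.37 (log2, SE), with Nusap1 at 4.01 without WT replicate 2. Oog4, Tada1, Ppil4, Cept1, Frg1 and Fbxw22 rose by between 2.34 and 3.91. The count rests on the spread borrowed from the HET embryos: a fit of the 4 WT and KO embryos alone called 312 genes, 80 higher and 232 lower. Without WT replicate 1 the count was 1134, and without KO replicate 1 it was 1126.

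**Figure D1:**
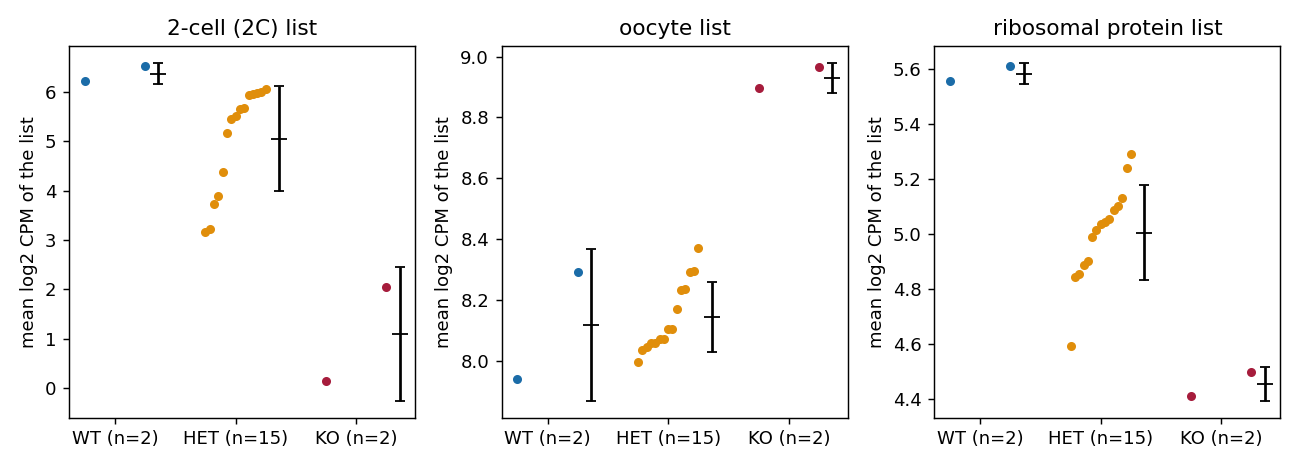
Mean log2 CPM of the 2-cell, oocyte and ribosomal protein lists (vertical axes) in each embryo of the WT, HET and KO groups (horizontal axis); each point is 1 embryo and the bar gives the mean ± SD. The KO embryos lay at 0.14 and 2.05 for the 2-cell list, against 6.21 and 6.52 in WT.

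KO embryos were next compared with HET embryos, which asks what separates homozygous from heterozygous crossings. Of 30 2-cell genes, 21 fell and 2 rose (camera adjusted p = 8.63e-10, and 0.285 with an estimated correlation). Zfp352 fell by 6.94 ± 0.75 on the log2 scale (SE, adjusted p = 6.92e-07, edgeR), and its log2 fold change was -5.92 without KO replicate 1. Of 54 oocyte transcripts, 23 rose and 0 fell, and this list also passed with an estimated correlation (adjusted p of 2.33e-10 with the preset and 0.0227 with the estimated correlation). Plat, the tissue plasminogen activator gene, rose from 37.6 ± 10.1 (SD, n = 15) to 238 ± 161 CPM (SD, n = 2), with the log2 fold change moving from 2.66 to 1.71 without KO replicate 2. Without KO replicate 1 only 7 2-cell genes fell and 11 oocyte transcripts rose. Of 15 cumulus markers 3 were higher and 1 lower (camera adjusted p = 0.498). Higher were Inha, with 0 counts in every HET embryo and in KO replicate 2 and 111 in KO replicate 1, Hsd3b1, with 131 counts in KO replicate 1 and 0 in KO replicate 2, and Cyp19a1, with edgeR adjusted p of 0.00398, 0.0191 and 0.0234. Without KO replicate 1, Inha had 0 counts in both groups and Hsd3b1 turned to a log2 fold change of -5.39 (adjusted p = 0.488). Cyp19a1 was higher in both KO embryos, with a log2 fold change of 1.71, and its call was lost without either, at 1.58 without KO replicate 1 (adjusted p = 0.252) and 1.83 without KO replicate 2 (adjusted p = 0.0939). Of 5 blood markers 0 were called and 4 had 0 counts in KO, and the list passed fry (adjusted p = 0.0308) but not camera (0.34). Of 3 oviduct markers 0 were called, and 2 were lower adjusted over the list alone, Ovgp1 from 3.12 ± 3.18 to 0.15 ± 0.21 CPM and Epcam from 10.55 ± 7.57 to 1.40 ± 1.98 CPM. Sperm markers had 0 of 7 called (camera adjusted p = 0.579). Stress genes, cleavage and lineage factors and regulators of Dux passed fry (adjusted p of 0.0164, 0.044 and 0.0413) but not camera. Targets of p53 had 3 higher and 2 lower of 24 (camera adjusted p = 0.965) and histones 3 higher of 22 (0.0808). Mitochondrial genes had 2 lower of 33 (0.579), mt-Rnr1 and mt-Rnr2 at -0.93 and -0.83 on the log2 scale, while the list median was -0.02. Nucleolar factors had 19 members higher and 4 lower of 59 (adjusted p = 0.00101, and 0.278 with an estimated correlation), with Ddx18 up by 1.36 ± 0.20 and the fibrillarin gene Fbl at -3.05 ± 0.48 (log2, SE), which was -2.23 without KO replicate 1 and -5.11 without KO replicate 2. The higher nucleolar members were 9 and 11 without these embryos. In the proteasome list 14 of 47 rose and 4 fell (adjusted p = 0.000809, and 0.201 with an estimated correlation), and 17 of 86 ribosomal protein genes fell and 3 rose (adjusted p = 0.00101, and 0.52 with an estimated correlation). Without KO replicate 2, 6 proteasome genes rose, and without KO replicate 1, 8 ribosomal protein genes fell. The Dux family, which holds the targeted gene, passed camera at an adjusted p of 0.0127, and 0.285 with an estimated correlation. Respiratory chain genes, with 12 higher and 2 lower of 78, passed at 0.0142, and this was lost with an estimated correlation (adjusted p = 0.54), with fry (0.252) and without KO replicate 1 (0.469).

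Over all genes, 2615 were called between KO and HET, 1271 higher and 1344 lower. Ssb, Frg1 and Pcgf1 rose by 2.86 ± 0.16, 3.75 ± 0.22 and 2.93 ± 0.20 (log2, SE), and the F-box gene Fbxw18 rose from 178 ± 49.6 to 1461 ± 142 CPM. Ypel5, Ppil4, Tacc3, Tdpx-ps1, Arl6ip1, Nusap1, Psma7 and Gm13103 also rose. Bex6 was at least 71.9-fold lower and Gm15455 at least 150.0-fold lower in KO, with bounds of 34.7 and 72.5 without KO replicate 1 and 37.2 and 77.8 without KO replicate 2. The centriole gene Cep135 fell from 99.7 ± 12.9 to 19.7 ± 1.57 CPM. Gcsh, B930036N10Rik, Gm13736, Gm16548, Gm15486, Pknox2, Pnpla3 and Zfp30 fell as well. Of these genes, Cep135, Pnpla3, Tdpx-ps1 and Gm13103 were not called between KO and WT (edgeR adjusted p of 0.894, 0.932, 0.265 and 0.174), and their WT means of 18.7, 1.79, 62.0 and 864 CPM stood nearer to KO, at 19.7, 1.61, 98.2 and 1206, than to HET, at 99.7, 51.1, 12.8 and 356. Without KO replicate 1 the count dropped to 908. Of the calls in both comparisons of KO, 630 genes were higher and 767 lower in each, against 75.2 and 85.2 for independent lists. In 20 simulations with no effect almost no gene was called, so lists of the same lengths were taken there by the smallest p, and they shared on average 354 higher and 600 lower genes. Part of the overlap may therefore come from the shared KO embryos, of which there are too few to split.

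In HET embryos part of the ribosomal protein genes were lower than in WT, while few 2-cell genes passed the test. Of 86 ribosomal protein genes, 14 fell and 1 rose, with a median log2 fold change of -0.53 (camera adjusted p = 8.52e-11, and 0.37 with an estimated correlation). Rpl29 fell from 15.4 ± 0.28 (SD, n = 2) to 0.86 ± 0.41 CPM (SD, n = 15), and Rpl21 fell by 2.01 ± 0.45 (log2, SE), a call lost without WT replicate 2 (adjusted p = 0.129). Without WT replicate 1 only 3 ribosomal protein genes fell, and without WT replicate 2 only 4. Of 30 2-cell genes, 0 fell and Pramef12 rose, although the list passed camera with a median of -0.98 (adjusted p = 0.00265); with an estimated correlation its adjusted p was 0.89, with fry it was 0.43, and without WT replicate 2 it was 0.345. Oocyte transcripts had 4 higher and 5 lower of 54, with Tcl1 at -0.95 ± 0.14 and Rfpl4 at 0.73 ± 0.16 (log2, SE). Their median log2 fold change was -0.03, moving to -0.16 without WT replicate 1 and to 0.17 without WT replicate 2. The calls of Pramef12 and Rfpl4 were lost without WT replicate 1 (adjusted p of 0.232 and 0.108) and without WT replicate 2 (0.103 and 0.0598). Over all genes, 1012 were called, 584 higher and 428 lower in HET, and the larger side turned with DESeq2 size factors, to 489 higher and 535 lower, and with no count filter, to 567 and 646. Cep135 rose from 18.7 ± 2.98 to 99.7 ± 12.9 CPM and C87977 from 315 ± 147 to 1503 ± 208 CPM. Pnpla3, Rpia, Ankrd17, Anln, Spopl, Arntl, Synj1, Fgd6, Insm1 and Trim32 also rose. The ETS family gene Spic and the malic enzyme gene Me1 fell, with log2 fold changes of -3.59 ± 0.37 and -1.95 ± 0.21 (SE). Spic stood at 114 ± 99.9 CPM in WT (SD, n = 2) and 9.46 ± 3.97 CPM in HET (SD, n = 15), and its log2 fold change was -2.22 without WT replicate 1 (adjusted p = 0.0341) and -4.28 without WT replicate 2. Tdpx-ps1, Gm13103, Rnpep, Grm2, Spcs2, Serpinc1, Oaz1, Tpm3 and Zfp791 fell too, Grm2 not without WT replicate 1 (adjusted p = 0.0505). Without WT replicate 1 only 200 genes were called. Of 15 cumulus markers 1 was lower in HET, Inha, with 23 counts in WT replicate 1 and 0 in WT replicate 2 and every HET embryo. The sperm, blood and oviduct lists had 0 members called. In WT replicate 1 the 10 most counted genes held 14.8% of the gene counts, against 9.43% in WT replicate 2 and 7.32% to 10.3% in HET. Since no 2 groups share a title M number, genotype and M number cannot be told apart in any of these comparisons.

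Within the HET group, the 5 embryos with the least Duxf3 had the lowest 2-cell list. Of them, replicates 3, 10 and 20 had 0 AW822073 counts and replicate 11 had 9. Replicate 15 had 31, at 3.96 CPM, above the 3.74 CPM of WT replicate 2, so its low Duxf3 level did not extend to AW822073. Gm4981 had 43, 36, 13, 16 and 19 counts in replicates 3, 10, 11, 15 and 20. In the other 10 embryos it had 15 to 78, with 15 in replicate 4 and 20 in replicate 6. The relations of AW822073 and Gm4981 to the list were not tested. Over the 15 embryos the correlation of log2(CPM + 1) of Duxf3 with the mean log2 CPM of the list was r = 0.80 (permutation p = 0.00069) and rho = 0.64 (permutation p = 0.0131). It was r = 0.80 (permutation p = 0.00118) within the 14 embryos of M number 2, and r = 0.75 without the 2 embryos farthest from the Duxf3 median. This was the 1 relation of the plan that was run, so its p is unadjusted. Of 2 subsets chosen after the values were seen, among the 12 embryos with over 1 Duxf3 count r was 0.67 (permutation p = 0.0171) and rho 0.36 (permutation p = 0.258), and r turned to -0.32 without the 2 embryos farthest from the Duxf3 median. The 10 left are those above the widest gap in the 2-cell list, the other subset, and also the 10 with the most Duxf3 (permutation p = 0.367). No rise of the list with Duxf3 was thus seen among these 10, so the relation over the 15 depends on the other 5. Below the gap lay replicates 3, 10, 11, 15 and 20, at 4.38, 3.17, 3.89, 3.23 and 3.73, while the other 10 lay between 5.17 and 6.04.

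**Figure D2:**
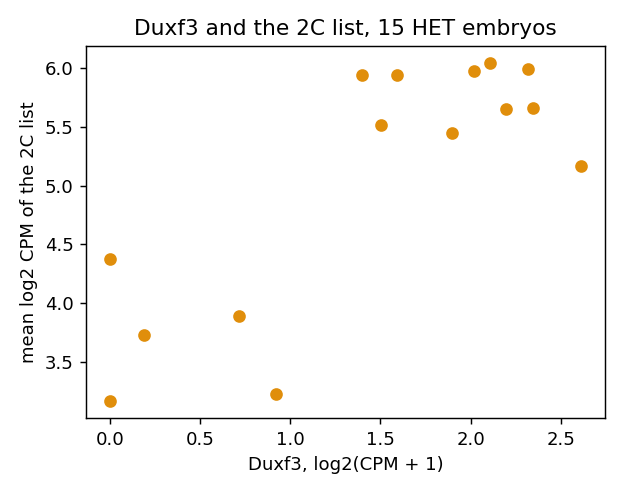
Duxf3 as log2(CPM + 1) on the horizontal axis against the mean log2 CPM of the 2-cell list on the vertical axis; each point is 1 of the 15 HET embryos. The 5 embryos with the lowest list values, at 4.38 or below, also hold the lowest Duxf3 values.

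Repeat copies took a smaller part of the reads in KO embryos. Repeat counts per 100 gene counts were 8.14 and 11.1 in KO, 15.99 and 13.7 in WT, and between 11.5 and 15.2 in HET. The KO mean of 9.63 was below the HET mean of 14.1 (exact permutation test, two-sided p = 0.0147, the smallest that 2 against 15 allows), and for KO against WT the exact permutation test cannot go below 0.333. Of 35967 copies tested, 2234 were lower and 215 higher in KO than in WT, 2616 lower and 439 higher in KO than in HET, and 71 lower and 70 higher in HET than in WT. Without KO replicate 1 the counts of called copies were 338 for KO against WT and 191 for KO against HET. The families these copies belong to were not analysed here.

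**Figure D3:**
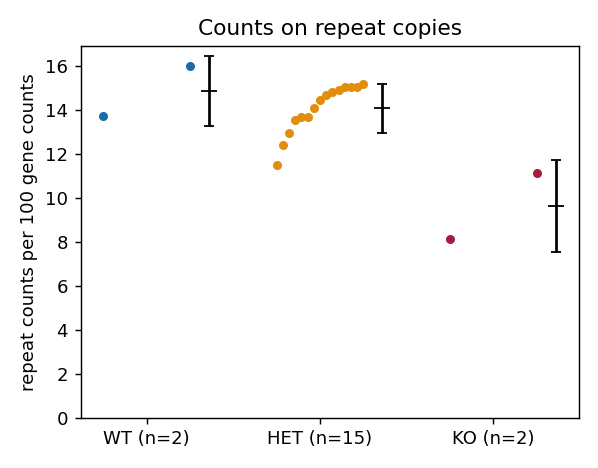
Counts on repeat copies per 100 gene counts (vertical axis) in each embryo of the 3 groups; each point is 1 embryo and the bar gives the mean ± SD. Both KO embryos, at 8.14 and 11.1, lie below every WT and HET embryo.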

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

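The repeat copy tests, the settings run on them, and both subsets of HET embryos in the Duxf3 relation were chosen after the data were seen; the other settings were fixed before. No cause was tested for the changes below. Fits with fewer embryos have less information on the spread. In the fit of all embryos the HET embryos set most of the spread, and the WT and KO pairs differed more than most HET pairs. The p-values of that fit for KO against WT may therefore be too small. Which of these reasons applies to the lost calls was not tested. Where a replicate was left out, the remaining embryo of that group was assumed to vary like the other groups. The repeat family and MERVL settings were not run, because the copies carry no names. The DESeq2 size factors moved the median of all genes by less than 0.1, but turned the larger side of the HET against WT calls, with 489 higher and 535 lower.

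Of the named genes under all settings, 2457 results kept their direction and side of the threshold, 198 lost the call, 39 gained it and 12 turned. The turned ones came from leaving out 1 embryo; of them, Hsd3b1 had been called for KO against HET and the others had not been called. Fitted log2 fold changes, several of them with a group at 0 counts and so set by the prior count, then ran as follows. For KO against WT they ran from -2.26 to 9.17 for Hsd3b1, lowest without KO replicate 1, from -8.46 to 6.49 for Epcam, highest without WT replicate 2, and from -3.63 to 3.36 for Ovgp1, which was 0.69 without KO replicate 1. For KO against HET they ran from -5.39 to 4.8 for Hsd3b1 and from -0.58 to 2.89 for Hist1h4n, lowest without KO replicate 1. For HET against WT, where the turn came without WT replicate 1, they ran from -3.58 to 0.36 for Krt8, -2.46 to 0.11 for Tnfaip6, -3.36 to 0.16 for Vcan, -1.86 to 0.033 for Lyz2, -0.055 to 9.38 for Epcam and -1.75 to 0.36 for mt-Co3.

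For KO against WT, the DESeq2 Wald test gave 1695 lower genes, and the fit of 2 groups gave 312 calls, 80 higher and 232 lower, 301 of them among the 2059. WT and KO embryos share replicate numbers but differ in M number. The deviations of same-numbered embryos had a correlation of 0.005, so no pairing by number was seen, but 2 embryos per group cannot exclude one. With a replicate block there were 269 calls, 69 higher and 200 lower. Duxf3 and AW822073 were then not called (edgeR adjusted p of 0.172 and 0.148), nor was Gm4981. Leaving out 1 embryo gave 1126 to 2060 calls, 440 to 1030 higher and 472 to 1068 lower. For KO against HET, the Wald test gave 2138 lower genes and leaving out 1 embryo gave 908 to 2744 calls, 557 to 1349 higher and 351 to 1449 lower. For HET against WT, the Wald test gave 1531 calls, 948 higher, no filter gave 567 higher and 646 lower, and leaving out 1 embryo gave 200 to 1268 calls, 132 to 679 higher and 68 to 615 lower.

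With an estimated correlation 0 of 5 lists passed for KO against WT, 1 of 7 for KO against HET and 0 of 2 for HET against WT. With fry 8 lists passed for KO against WT, 10 for KO against HET, 6 of the 7 calls among them, and 1 for HET against WT. Leaving out 1 embryo gave 4 to 8 lists for KO against WT, 6 to 10 for KO against HET and 2 to 3 for HET against WT. With the block 4 of the 5 lists for KO against WT were tested and kept their calls.

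For repeat copies the DESeq2 Wald test called 4163 for KO against WT, 582 higher and 3581 lower, 6286 for KO against HET, 5672 lower, and 667 for HET against WT, 538 higher and 129 lower. With the expression filter replaced by a minimum of 50 counts in total, 128 copies were lower for HET against WT. Leaving out 1 embryo gave 338 to 1583 copies for KO against WT, 50 to 80 higher and 288 to 1533 lower, 191 to 2709 for KO against HET, 49 to 487 higher and 142 to 2222 lower, and 28 to 282 for HET against WT, 9 to 81 higher and 19 to 201 lower. The difference in repeat counts per 100 gene counts ran from -5.92 to -2.96 for KO against HET, where 1 against 15 embryos cannot pass (exact permutation p = 0.125), from -6.71 to -3.75 for KO against WT, and from -1.93 to 0.35 for HET against WT, where it turned without WT replicate 1.

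The Duxf3 relation was r = 0.79 with CPM on raw totals and turned to -0.32 in the 10 HET embryos above the widest gap in the 2-cell list, which are also the 10 with the most Duxf3. The same value came from the 12 embryos with over 1 Duxf3 count without the 2 farthest from the Duxf3 median, so the relation was not seen without the 5 embryos lowest in both. Group means of Duxf3 moved by less than the spread between embryos on raw totals. Depth limits the Dux family, with at most 78 counts in any HET embryo, and most repeat copies.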

Other observations

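The family enrichments, the permutation tests per embryo on lists, and the tests on single HET embryos, on oocyte genes and on the M number were chosen after the results were seen; those on the spread of the HET embryos and the random lists for ribosomal protein genes were set before.

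Apart from the fixed lists, gene families sharing a symbol stem were tested for enrichment among the calls with Fisher's exact test, over 372 tests per comparison. Some members, among them Fbxw16, Fbxw20 and Obox1, also belong to the oocyte list, so the families partly repeat it. Of 19 tested Fbxw genes, F-box genes with many oocyte-expressed members, 10 were higher in KO than in WT against 1.12 by chance (adjusted p = 5.25e-06), and 10 were higher in KO than in HET (adjusted p = 0.000108). Of 22 Obox genes, a homeobox family, 9 were lower in KO than in WT (Fisher adjusted p = 0.000455). Obox1 instead rose by 1.33 ± 0.20 on the log2 scale, a call lost in the fit of WT and KO alone (edgeR adjusted p = 0.139). The same family did not pass for KO against HET, with 7 lower (adjusted p = 0.149). Of 13 Naa genes, subunits of N-terminal acetyltransferases, 6 were higher in KO than in WT (adjusted p = 0.00375), but the 4 higher in KO than in HET did not pass (adjusted p = 0.671). Members of a family can share reads, so their calls are not independent. Counts on 4 Y-linked genes exceeded 10 in 9 of the 15 HET embryos and did not exceed 2 in any WT or KO embryo. Xist had 34 and 36 counts in the WT embryos and 0 in both KO embryos. It had 9 to 89 counts in the HET embryos with 0 Y-linked counts and 0 to 54 in the others. The KO embryos had 0 and 2 Y-linked counts, so their sex cannot be read from these genes. Both WT embryos had 0 Y-linked counts, unlike 9 of the HET embryos, and sex was in no model. Whether sex carries a part of the differences between HET and WT was not tested.

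The HET embryos were uneven in the 2-cell list. The SD of the list mean between them was 1.06, above all 1000 random lists matched on expression (percentile 100), and their Duxf3 levels ran from 0, as in KO, to within the WT range. Their 2-cell list means, from 3.17 to 6.04, reached neither the KO values of 0.14 and 2.05 nor the WT values of 6.21 and 6.52, and any list of jointly regulated genes would exceed random lists. Whether the label is that of the parents and the group holds several genotypes stays open. The 3 embryos with at most 1 Duxf3 count did not lack Duxf3, AW822073 and Gm4981 together, as the KO embryos did, since the lowest Gm4981 count among them was 19. The list did not rise with depth, as it would if depth set its level. Spearman's rho of the list with the gene count total was -0.458 (permutation p = 0.0873), and a relation in this other direction stays open. Progress of genome activation also stays open as a source, with a rho of 0.15 with the nucleolar list (permutation p = 0.595).

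Of 86 ribosomal protein genes, 14 were lower in HET and 35 in KO than in WT, and the list calls were lost with an estimated correlation (adjusted p of 0.37 and 0.178). They have short transcripts by annotation: the longest one per gene had a median of 1054 bases against 3038 for all tested genes. A candidate explanation was therefore that short transcripts were captured less in HET and KO libraries. Their median for HET against WT lay at percentile 0 of 10000 random lists matched on length and expression, and, as a test of GC content bias, at percentile 0 of lists matched on GC content and expression, and per embryo the list less its length-matched genes was lower in HET by an amount that separated all embryos (exact permutation p = 0.0147, the smallest possible). The lists matched on GC content gave the same exact permutation p. Joint regulation can by itself place a list outside random lists, so the percentiles alone do not decide. For HET against WT the exact test argues against length or GC content, measured on the longest annotated transcript, as the whole cause. That transcript need not be the one expressed, so a length effect can survive the matching. For KO against WT the exact permutation test cannot go below 0.333. The matched lists on length had a median of -0.10, so length may carry a part. The M number is shared by 0 of the 3 pairs of groups, so a difference between collections or crosses and an effect of genotype cannot be told apart.

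The higher oocyte genes in KO were set against a common rise of all transcripts that did not fall, with random lists drawn from genes not called lower. For KO against HET the list median lay at percentile 100 of lists matched on expression. Against lists matched on length and expression it lay at 99.97. The list less its matched genes separated the embryos (exact permutation p = 0.0147, the smallest possible). The oocyte list thus rose beyond matched genes not called lower. That pool can still hold fallen genes, since the simulated test recovered only 43.3% of changes of 2 on the log2 scale. Such genes would lower the random lists, so scaling or length as the whole cause stays open there. For KO against WT the percentiles were 98.9 and 97.4, the latter within the 95% range, and 2 against 2 embryos cannot go below an exact permutation p of 0.333, so both remain open. A slower loss of maternal RNA in KO and a difference in the time of collection also remain open and untested, as does the M number, with 0 shared pairs of groups.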
